A study of Homo sapiens with 8 samples.

How the data were processed

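Gene expression was measured by RNA sequencing in PANC-1 and AsPC-1, each cultured for 24 h as control (pH 7.4), at low pH (6.8), under nutrient starvation or under hypoxia (oxygen of 1%), with 10% serum and 5% CO2. Each line and condition has 1 library, made from 1 µg of total RNA with a TruSeq kit per the labels. Per the submitters' processing notes, reads were aligned with BWA to UCSC transcripts and to the GRCh37/hg19 genome, and realigned locally with an in-house aligner of k-mer size 11. Versions, trimming, strand protocol and the handling of reads with several matches are not stated.

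The deposited FPKM values were made by the authors per UCSC transcript and strand, scaled to exon length and library size. They equal aligned bases divided by exon length and by a library total of bases, which was checked in each file. The deposited coverage column (signal) holds aligned bases over the exons of a transcript, counted by the authors and not normalized, and not read counts. The deposited log10 column is the log10 of the FPKM made by the authors, with 0 set to -5. The deposited log2 column is the log2 of the FPKM made by the authors, with 0 set to -16. Each file holds 173634 entries, of which 86817 on the sense strand were used, and the antisense entries served only as a check of each library.

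The library total of mapped bases in Gb was 19.2, 11.8, 5.43 and 5.63 for control, low pH, starvation and hypoxia in PANC-1, and 6.31, 9.11, 8.78 and 19.5 in AsPC-1. If a fragment gives 200 aligned bases, 1 FPKM on a transcript of 1 kb rests on 95.8, 58.9, 27.1 and 28.2 fragments in PANC-1 and on 31.6, 45.6, 43.9 and 97.4 in AsPC-1. Values well under 1 FPKM therefore rest on few fragments. The strand split of the values was taken from the files, and a strand-specific kit is not described.

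Of several transcripts with the same symbol, the one with the highest mean FPKM over the 8 libraries stood for the gene. Of 38368 symbols, 14678 had a mean FPKM of at least 1 and were tested. Symbols are those of the files, some of which are old names or overlapping entries of the same locus. The values were log2(FPKM + 1). limma 3.58.1 (R 4.3.3) fitted cell line and culture condition over all 8 libraries, with an intensity trend in the variance prior, 3 residual degrees of freedom and 9.18 prior ones. Tests were 2-sided and adjusted by the method of Benjamini and Hochberg at 0.05, over all genes, and separately over each gene list alone. The SE beside a log2 fold change is that of limma. It rests on 1 error per gene shared by all conditions, so disagreement of the lines under 1 stress enters the SE of the others. Tested on simulated data with 100 genes changed 4-fold and 100 changed 2-fold, the model recovered 95, 92 and 89 of the former and 13, 15 and 16 of the latter for low pH, starvation and hypoxia, with 8, 8 and 9 false calls. The simulation used independent normal noise, no effect of the other conditions and the same response in both lines. Its recovery can exceed that in the data, so an absence of calls does not show that no gene changed 4-fold.

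Before the data were examined, 35 gene lists were fixed. Of their 855 members, 836 were matched by symbol, 7 by RefSeq accession and 12 not at all. The 30 lists with at least 5 tested genes were tested with limma camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, adjusted over the lists of a condition. Medians of lists in a single line were set against 10000 random lists matched on 20 classes of expression. Within a line, and between the lines, log2 fold changes were described without a test, counting genes that moved at least 2-fold. The counts expected for independent lists are the products of the shares of both lines.

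The genes named were chosen by a rule fixed beforehand. It takes, per condition, the 8 highest and 8 lowest genes past the threshold or, where fewer passed, those with the largest smaller change of both lines, up to 4 members of each list discussed, and a panel of 10 genes, of which 9 were used here. It further takes the 5 genes per direction that differ most between the lines at a mean FPKM of at least 5, and the 8 per direction with the largest gap between AsPC-1 and PANC-1. List members past the threshold over their list alone, genes behind counts of 5 or fewer, and members of marker lists were named after their values were seen.

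The alternatives were pseudocounts of 0.1 and 5, no filter on low values, a mean FPKM of at least 5, TMM scaling (trims of 30 and 5 percent), quantile normalization, the sum of the entries of a symbol, only the 4 libraries of a comparison, no cell line term, no intensity trend, a robust variance prior, and leaving out each library in turn. Added after the data were seen were a GC correction, the same without the PANC-1 hypoxia library, the transcript chosen by the authors for a symbol, and genes taken by RefSeq accession. The GC correction subtracted, in each library, a lowess curve (span 0.3) of the log2 value minus the line mean on the GC content of the best overlapping GENCODE transcript, which 13757 genes (93.7%) had at a minimum Jaccard overlap of 0.5. Other computations used data.table (version 1.17.8), Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.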

Results

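RNA from PANC-1 and AsPC-1, both human pancreatic cancer cell lines, was sequenced after 24 h in 4 culture conditions. These were a control at pH 7.4, low pH at 6.8, nutrient starvation, and hypoxia at an oxygen level of 1%. The starvation medium is a 100-fold nutrient dilution in the treatment protocol and a 1000-fold dilution in the sample labels, so its strength is uncertain. Each line and condition has 1 library, 8 in all, and there are no replicates within a line. An effect of a condition was therefore tested over both lines together, and values of 1 line are given without a test. The exception is fits that leave out a library of the condition or its control, which rest on 1 line for that side. Their p-values and counts take their error from the other libraries and are not replicated over both lines. The conditions of a line share its control library, so results that recur across conditions are not independent. In fits over all 8 libraries they also share 1 error per gene, so an SE is not the spread of its condition alone. The PANC-1 libraries held 19.2 Gb of mapped bases for the control, 11.8 Gb for low pH, 5.43 Gb for starvation and 5.63 Gb for hypoxia. The AsPC-1 libraries held 6.31 Gb, 9.11 Gb, 8.78 Gb and 19.5 Gb in the same order. Between 12619 genes in the AsPC-1 low pH library and 14554 in the PANC-1 starvation library reached 1 FPKM. Entries antisense to a gene, which no comparison used, held 1.08% of aligned bases in the AsPC-1 low pH library and between 1.44% and 1.81% in the other 7.

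Low pH was set against control to ask what acid medium does to gene expression. Keratin genes of simple epithelia were lower at low pH in both lines. KRT8 (chromosome 12, 53290971 to 53298868, GRCh37) measured 1120.3 FPKM in the PANC-1 control and 241 FPKM at low pH, and 1093 and 172 FPKM in AsPC-1. Its mean log2 fold change was -2.44 ± 0.54 (SE of the limma model, n = 2 lines), beside -2.15 ± 0.47 for KRT19 and -1.74 ± 0.39 for KRT18. Of 19 measured epithelial genes, these 3 fell when adjusted over the list alone (limma, Benjamini-Hochberg adjusted p = 0.00464), and 0 passed over all genes. The list median was -0.50 (camera adjusted p = 0.00348, adjusted p = 0.654 with an estimated correlation), -0.01 in PANC-1 and -0.995 in AsPC-1, with 9 genes lower and 2 higher in both lines. After the GC correction it was -0.15 (camera adjusted p = 0.0175, adjusted p = 0.689 with an estimated correlation), 0.048 in PANC-1 and -0.63 in AsPC-1, and 3 genes fell over the list alone. Over the list alone, 0 members passed without the PANC-1 control, the AsPC-1 control or the AsPC-1 low pH library, and 5 fell without the PANC-1 low pH library. Without the AsPC-1 control the camera call also ended, at a median of -0.12 (adjusted p = 0.114), and with no filter on low values 0 members passed and the call ended too (adjusted p = 0.0622). With no cell line term 0 members passed over the list alone. The ductal markers, a list of 12 measured genes that shares KRT7, KRT19 and MUC1 with the epithelial one, had a median of -0.40 (camera adjusted p = 0.00809, adjusted p = 0.654 with an estimated correlation), -0.09 in PANC-1 and -0.87 in AsPC-1. In the ductal list KRT19 alone fell when adjusted over the list alone, and AGR2, a secretory protein disulfide isomerase, was at -2.25 ± 0.76. Without either control 0 ductal genes fell over that list alone, 2 without the PANC-1 low pH library, 3 without either starvation library, and 0 with no filter on low values or no cell line term. That ductal call ended without the AsPC-1 control, at a median of -0.27 (adjusted p = 0.1), after the GC correction, at -0.14 (adjusted p = 0.0984), and with no cell line term (adjusted p = 0.107).

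Cholesterol genes went both ways at low pH, more of them up. Of 26 measured genes of sterol synthesis and its SREBP2 control, 14 were higher in both lines and 8 lower in both, 5 rose and 1 fell when adjusted over the list alone, and 0 passed over all genes. The sterol carrier gene STARD4 rose by 1.62 ± 0.38 on the log2 scale, the methylsterol oxidase SC4MOL (now MSMO1) by 1.45 ± 0.36 and squalene epoxidase SQLE by 1.42 ± 0.43. IDI1 rose by 1.41 ± 0.40 and INSIG1 by 1.29 ± 0.36, whereas PMVK, a kinase of the mevalonate pathway, fell by 1.48 ± 0.44. HMGCS1, the synthase at the head of the pathway, was at 0.94 ± 0.36. The list median was 0.33 (camera adjusted p = 0.00563, adjusted p = 0.654 with an estimated correlation). Without the AsPC-1 low pH library it was 0.18 and the call ended (adjusted p = 0.0961), and 0 members passed over the list alone without that library, without either control, with no filter on low values or with no cell line term. Over the list alone 8 rose and 1 fell after the GC correction.

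Cell cycle genes split by phase at low pH. Among 37 measured genes of DNA replication, 29 were below control in both lines, and MCM3 and UHRF1 fell when adjusted over the list alone, by 1.56 ± 0.34 and 1.36 ± 0.34. MCM3 is a subunit of the replicative helicase and went from 81.8 to 32.1 FPKM in PANC-1 and from 38.8 to 10.5 FPKM in AsPC-1. The replication list had a median of -0.59 (camera adjusted p = 1.55e-07, adjusted p = 0.55 with an estimated correlation). Among 40 genes of mitosis, 29 were above control in both lines, and CDC25C, a phosphatase of mitotic entry, rose by 1.44 ± 0.33 when adjusted over the list alone. The mitosis list had a median of 0.51 (camera adjusted p = 5e-07, adjusted p = 0.654 with an estimated correlation), 0.27 in PANC-1 and 0.68 in AsPC-1. In both lists 0 members passed over all genes, and over the list alone 0 passed without either control or either low pH library. Without either hypoxia library 14 replication genes fell and 4 mitosis genes rose. With no cell line term 0 members of both lists passed over the list alone. In the mitosis list 0 also rose with the sum of the entries of a symbol, with the transcript chosen by the authors, or after the GC correction, which could not include CDC25C for lack of a GC value, and 6 replication genes fell after that correction.

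Growth and energy genes were mostly lower at low pH. The 73 cytosolic ribosomal protein genes had a median of -0.65 (camera adjusted p = 6.69e-11), -0.23 in PANC-1 and -1.07 in AsPC-1. Of them 60 were lower in both lines. The 50 nuclear genes of oxidative phosphorylation had a median of -0.55 (camera adjusted p = 9.5e-07), -0.31 in PANC-1 and -0.77 in AsPC-1. Of them 40 were lower in both lines. The 19 glycolysis genes had a median of -0.81 (camera adjusted p = 0.000146), with 14 lower in both lines, ENO1 at -1.17 ± 0.46, PKM2 at -1.09 ± 0.37 and the lactate exporter SLC16A3 at -1.28 ± 0.56. For these 3 lists the adjusted p = 0.654 with an estimated correlation, and 0 members passed over all genes or when adjusted over the list alone. The 35 genes of ribosome biogenesis had a median of -0.37 (camera adjusted p = 0.0014, adjusted p = 0.55 with an estimated correlation), and NOP56 alone fell over that list alone, by 1.38 ± 0.31. NOP56 did not pass without either control, either low pH library or the cell line term, and 3 genes of that list fell without either hypoxia library. Heat shock genes, 17 in number, had a median of -0.34 (camera adjusted p = 0.0354, adjusted p = 0.654 with an estimated correlation), -0.51 in PANC-1 and -0.12 in AsPC-1, with 11 lower in both lines. That heat shock call ended without the PANC-1 low pH library, at -0.11 (adjusted p = 0.948), without the AsPC-1 control, at -0.27 (adjusted p = 0.114), and under quantile normalization, at -0.12 (adjusted p = 0.127). It also ended with a pseudocount of 0.1 (adjusted p = 0.076) and with the transcript chosen by the authors (adjusted p = 0.0602).

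Stress response genes were among those above control at low pH. The 22 genes of the unfolded protein response of the endoplasmic reticulum had a median of 0.54 (camera adjusted p = 0.000132, adjusted p = 0.55 with an estimated correlation), 0.22 in PANC-1 and 0.83 in AsPC-1. Of them 16 were higher in both lines, and the chaperone gene HSPA5 was at 1.04 ± 0.31. The 23 autophagy genes had a median of 0.25 (camera adjusted p = 0.00809, adjusted p = 0.55 with an estimated correlation), with 13 higher in both lines and MAP1LC3B at 1.10 ± 0.43. The 30 genes of the ATF4 amino acid response had a median of 0.45 (camera adjusted p = 0.00809, adjusted p = 0.654 with an estimated correlation), 0.57 in PANC-1 and 0.04 in AsPC-1, with 14 higher in both lines and 7 lower in both. A list of 23 targets of FOXO and MondoA had a median of 0.15 (camera adjusted p = 0.00934, adjusted p = 0.55 with an estimated correlation), with 9 higher in both lines and the glucose-sensing arrestin gene TXNIP at 1.44 ± 0.42. In these 4 lists 0 members passed over all genes or when adjusted over the list alone, while after the GC correction 4 genes of the unfolded protein response rose over their list alone. Without the PANC-1 low pH library the ATF4 median was -0.08, and without the AsPC-1 control the ATF4 call ended at 0.35 (adjusted p = 0.114) and the autophagy call at 0.18 (adjusted p = 0.0989). The FOXO and MondoA call ended without the PANC-1 control, at 0.29 (adjusted p = 0.0697), without the PANC-1 low pH library, at 0.13 (adjusted p = 0.0702), and with no cell line term (adjusted p = 0.107).

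Interferon response genes were below control mainly in AsPC-1. All AsPC-1 values at low pH rest on a library with the smallest antisense share (1.08%) and the fewest genes at 1 FPKM (12619). The 25 measured genes had a median of -0.45 (camera adjusted p = 0.0444, adjusted p = 0.654 with an estimated correlation), which was -0.04 in PANC-1 and -1.20 in AsPC-1, and the difference was not tested. Without the AsPC-1 low pH library the median was 0.0062, and the call ended without the AsPC-1 control at -0.30 (adjusted p = 0.545) and without either hypoxia library at -0.45 (adjusted p = 0.0658). The interferon median was -0.40 after the GC correction (adjusted p = 0.144). The interferon call also ended with a pseudocount of 5 (adjusted p = 0.108), no filter on low values (0.276), a mean of at least 5 FPKM (0.121), the sum of the entries of a symbol (0.0682), no cell line term (0.133), the transcript chosen by the authors (0.0602) and genes by RefSeq accession (0.103). Of 11 measured genes of pH regulation, the bicarbonate cotransporter SLC4A7 rose by 1.30 ± 0.38 and the anion exchanger SLC4A2 fell by 1.64 ± 0.43 when adjusted over the list alone, and 0 passed over all genes. That list was not called (camera adjusted p = 0.323). Neither SLC4A7 nor SLC4A2 passed without either control or the AsPC-1 low pH library, and SLC4A7 did not without the PANC-1 low pH library, while 2 fell without either hypoxia library. With no cell line term 0 passed over that list alone, and with no filter on low values 1 rose and 0 fell. Carbonic anhydrase CA9 was listed at 0 in both PANC-1 libraries and went from 8.46 to 3.90 FPKM in AsPC-1. The other panel genes not given above were ASNS at 0.74 ± 0.42, DDIT3 at 0.79 ± 0.41, NDRG1 at 0.66 ± 0.48, VEGFA at 0.47 ± 0.40, ACSS2 at 0.14 ± 0.34 and MKI67 at 0.59 ± 0.41.

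Over all 14678 genes, limma called 0 at an adjusted p under 0.05 at low pH, with a smallest adjusted p of 0.480, and 1304 at an unadjusted p under 0.05. After the GC correction 1884 of 13757 genes had an unadjusted p under 0.05 (limma) and 0 were called. A fit to only the 4 libraries of this comparison called 351 genes, 138 higher and 213 lower. KRT8 was the 1 gene called without the PANC-1 starvation library (adjusted p = 0.0428) or without the AsPC-1 starvation library (adjusted p = 0.0487). The unadjusted count was 333 without the AsPC-1 control, 262 without the AsPC-1 low pH library, 2450 without the PANC-1 hypoxia library and 2463 without the AsPC-1 hypoxia library. Counted without a test, 196 genes moved at least 2-fold the same way in both lines. Of these, 69 were higher and 127 lower, where independent lists of the 2 lines would share 13.8 and 37.6. Quantile normalization gave 101 higher and 90 lower, and the GC correction 46 and 57. In PANC-1 alone 261 genes were higher and 331 lower by at least 2-fold, and in AsPC-1 777 and 1667. The genes highest in both lines included the cystathionine lyase CTH at 1.45 ± 0.36 and the zinc finger gene ZNF550 at 1.60 ± 0.35. FAM72A, FAM72B and FAM72C, at 1.68 ± 0.42, 1.55 ± 0.37 and 1.63 ± 0.39, are near-identical copies on chromosome 1, with a further copy named after a clone, so reads cannot be assigned to 1 copy with certainty. KIAA1718 and JHDM1D (now KDM7A) share the start 139784548 on chromosome 7 and are 1 locus, at 1.45 ± 0.48 and 1.45 ± 0.47. Below control stood KRT8 and KRT19 with CABLES1 at -2.02 ± 0.59, TSPAN15 at -1.83 ± 0.47, the nuclear lamin gene LMNA at -1.71 ± 0.54 and the imprinted gene MEST at -1.70 ± 0.36. The entry named JUP, at -2.12 ± 0.47, begins at the first base of KRT19 (39679870) and spans it, so its values cannot be given to JUP. Fold changes at low pH were lower where transcripts held more GC, with a Spearman rho across genes of -0.485 in PANC-1 and -0.350 in AsPC-1. KRT8, with a transcript of 59.3% GC, was at -2.06 after the GC correction.

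**Figure D1:**
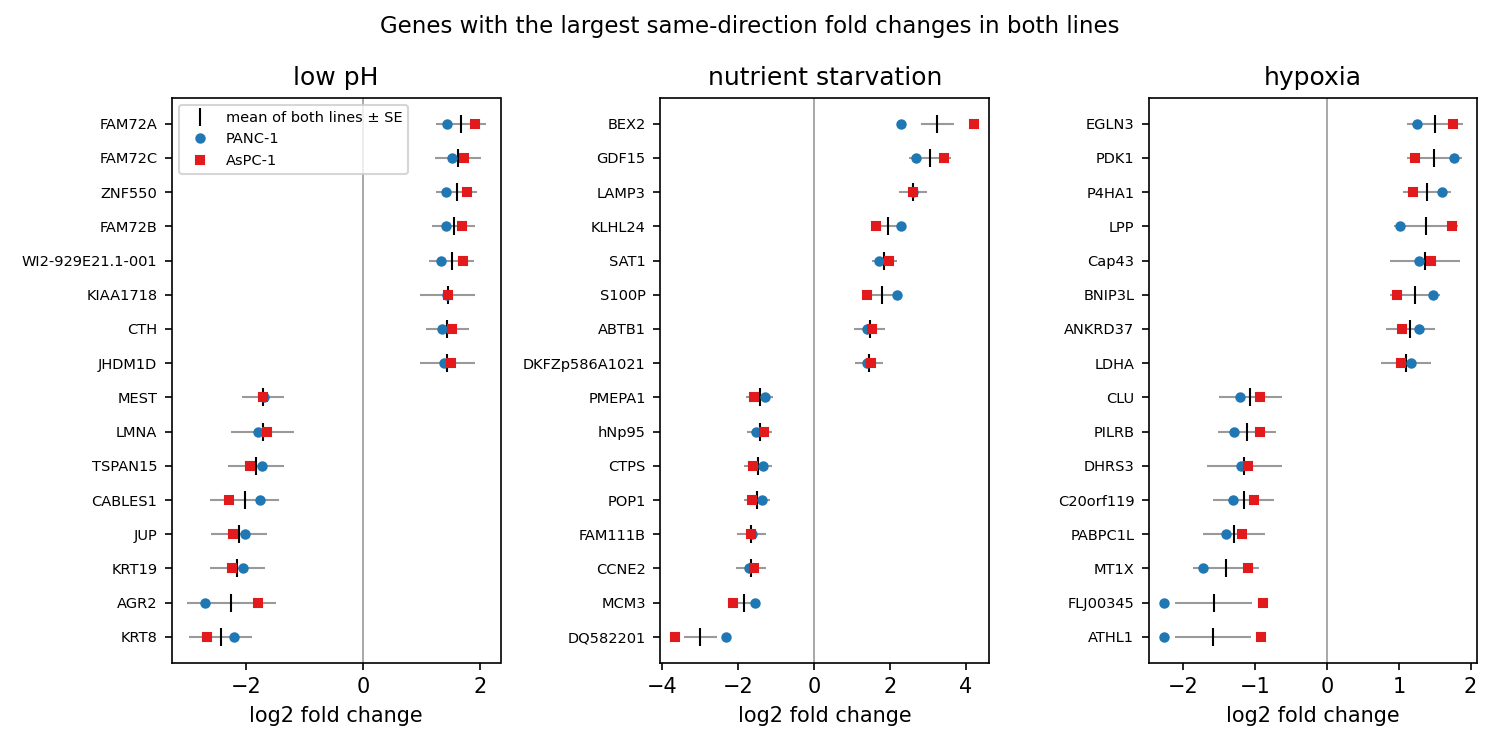
Log2 fold change against control (x axis) of the 8 highest and 8 lowest genes per condition by the rule fixed beforehand; circles are PANC-1, squares AsPC-1, ticks the limma mean of both lines and bars its SE. None passed over all genes; KRT8 at low pH stands at -2.44, GDF15 under starvation at 3.06 and EGLN3 under hypoxia at 1.50.

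Nutrient starvation was set against control to ask how diluted nutrients alter expression. Most genes of the amino acid response, targets of the transcription factor ATF4, were above control, 22 of 30 in both lines, while 1 was lower in both. GDF15, a stress cytokine gene (chromosome 19, 18496968 to 18499986), went from 4.66 to 35.4 FPKM in PANC-1 and from 0.680 to 17.2 FPKM in AsPC-1, a log2 fold change of 3.06 ± 0.55 (SE, n = 2 lines). Of 30 measured members, 9 rose when adjusted over the list alone and 0 over all genes (limma, Benjamini-Hochberg). They included the pseudokinase gene TRIB3 at 2.39 ± 0.55, NUPR1 at 2.34 ± 0.60, CHAC1 at 1.90 ± 0.51, DDIT3 at 1.71 ± 0.41 and asparagine synthetase ASNS at 1.46 ± 0.42. The list median was 0.88 (camera adjusted p = 1.13e-17, adjusted p = 0.337 with an estimated correlation), 0.53 in PANC-1 and 1.30 in AsPC-1. Over the list alone, 3 rose without the PANC-1 control, 0 without the AsPC-1 control, 2 without the AsPC-1 starvation library and 14 without the PANC-1 starvation library. With no filter on low values or no cell line term 0 rose over the list alone, under quantile normalization 16 and after the GC correction 13.

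DNA replication genes were below control under starvation. Of 37 measured genes, 34 were lower in both lines, 18 fell when adjusted over the list alone and 0 over all genes. MCM3 fell by 1.84 ± 0.34, from 81.8 to 27.2 FPKM in PANC-1 and from 38.8 to 8.13 FPKM in AsPC-1. The uracil glycosylase gene UNG fell by 1.70 ± 0.43, the S phase cyclin gene CCNE2 by 1.65 ± 0.40 and the replisome gene GINS2 by 1.47 ± 0.37. The list median was -0.89 (camera adjusted p = 6.48e-24, adjusted p = 0.157 with an estimated correlation), -1.17 in PANC-1 and -0.57 in AsPC-1. Over the list alone, 2 fell without the PANC-1 control, 0 without the AsPC-1 control, 4 without the PANC-1 starvation library and 0 with no cell line term, while 11 fell with no filter on low values. The 40 mitosis genes had a median of -0.27 (camera adjusted p = 0.0165, adjusted p = 0.903 with an estimated correlation), -0.46 in PANC-1 and -0.03 in AsPC-1, with 21 lower in both lines. In the mitosis list 0 members passed over all genes or when adjusted over the list alone. Without the PANC-1 starvation library the mitosis median was 0.04, and the call ended without the PANC-1 control, at -0.23 (adjusted p = 0.526), under quantile normalization, at -0.12 (adjusted p = 0.18), and at a mean of at least 5 FPKM (adjusted p = 0.0758).

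Most ribosome biogenesis genes were below control in both lines under starvation. The 35 genes of ribosome biogenesis had a median of -0.58 (camera adjusted p = 5.82e-09, adjusted p = 0.157 with an estimated correlation), with 30 lower in both lines and NOP56 at -1.16 ± 0.31. In that list 0 members passed over all genes or when adjusted over the list alone, while 6 fell over the list alone after the GC correction. The 17 heat shock genes had a median of -0.78 (camera adjusted p = 8.55e-08, adjusted p = 0.419 with an estimated correlation), with 15 lower in both lines. Over that list alone the mitochondrial chaperonin gene HSPE1 fell by 1.51 ± 0.40 and HSP90AA1 by 1.13 ± 0.34. Over the heat shock list alone, 0 passed without the AsPC-1 control, either low pH library or the AsPC-1 starvation library, 1 without the PANC-1 control, and 5 without the PANC-1 starvation library or either hypoxia library. With a pseudocount of 0.1 or of 5, with no filter on low values, with no cell line term or without the intensity trend 0 heat shock genes passed over that list alone. Under quantile normalization 1 did, while 3 fell after the GC correction and 5 with the transcript chosen by the authors. The 50 oxidative phosphorylation genes had a median of -0.43 (camera adjusted p = 2.66e-07), the 22 genes of the TCA cycle -0.33 (camera adjusted p = 0.00653) and the 19 glycolysis genes -0.34 (camera adjusted p = 0.00526). For these 3 lists the adjusted p = 0.726 with an estimated correlation, and 0 members passed over all genes or when adjusted over the list alone, while 4 glycolysis genes fell over their list alone after the GC correction. In PANC-1 the medians of oxidative phosphorylation and of the TCA cycle were both -0.083, above those of 63.9% and 57.0% of random lists of like expression, and in AsPC-1 they were -0.85 and -0.67, a difference that was not tested. The glycolysis medians were -0.37 and -0.36. LDHA, lactate dehydrogenase A, was at -1.07 ± 0.34 and PGK1 at -1.07 ± 0.34. Without the AsPC-1 starvation library the oxidative phosphorylation call ended at -0.19 (adjusted p = 0.246) and the TCA cycle call at -0.13 (adjusted p = 0.499). The glycolysis call ended without the PANC-1 control, at -0.33 (adjusted p = 0.181), and the TCA cycle call under quantile normalization, at -0.20 (adjusted p = 0.0848).

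Lists of catabolic genes had medians above control under starvation. The 23 targets of FOXO and MondoA had a median of 0.44 (camera adjusted p = 8.8e-07, adjusted p = 0.157 with an estimated correlation), with 13 higher in both lines, and the cyclin G2 gene CCNG2 rose by 1.60 ± 0.36 when adjusted over the list alone. CCNG2 did not pass without either control or the AsPC-1 starvation library, 2 members rose without the PANC-1 starvation library, and 3 rose without either hypoxia library. With no filter on low values or no cell line term 0 members rose over the list alone, and 3 after the GC correction. The 23 autophagy genes had a median of 0.36 (camera adjusted p = 5.89e-05, adjusted p = 0.157 with an estimated correlation), with 12 higher in both lines and MAP1LC3B at 1.54 ± 0.43. The 38 lysosome genes had a median of 0.30 (camera adjusted p = 0.000193, adjusted p = 0.337 with an estimated correlation), with 26 higher in both lines and the sterol carrier gene NPC2 at 1.13 ± 0.36. That lysosome call ended without the PANC-1 starvation library, at 0.21 (adjusted p = 0.0589). The 22 genes of the unfolded protein response had a median of 0.16 (camera adjusted p = 0.0158, adjusted p = 0.702 with an estimated correlation), -0.05 in PANC-1 and 0.34 in AsPC-1, with 9 higher in both lines and 7 lower in both, and HSPA5 was at 1.01 ± 0.31. In the autophagy, lysosome and unfolded protein lists 0 members passed over all genes or when adjusted over the list alone, while 4 autophagy genes and 4 unfolded protein genes rose over their lists alone after the GC correction. The call of the unfolded protein response ended without the AsPC-1 control, at 0.04 (adjusted p = 0.321), without the AsPC-1 starvation library, at 0.01 (adjusted p = 0.26), and with no filter on low values (adjusted p = 0.0528). S100P, a calcium-binding protein of ductal tumours, rose by 1.80 ± 0.44 when adjusted over the ductal list alone, in which 0 rose without either control, 0 rose and 2 fell without the PANC-1 starvation library, and 2 rose without the AsPC-1 starvation library. With no filter on low values or no cell line term 0 ductal genes rose over that list alone. The ductal list itself was not called (camera adjusted p = 0.555).

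Over all 14678 genes, limma called 0 at an adjusted p under 0.05 under starvation, with a smallest adjusted p of 0.0758, and 836 at an unadjusted p under 0.05. LAMP3, a lysosomal membrane protein gene, was at 2.62 ± 0.36 and the X-linked BEX2 at 3.25 ± 0.44, both with an adjusted p of 0.0758. A mitochondrial RNA, DQ582201 (mitochondrial genome, 237 to 368), was at -2.99 ± 0.44 (adjusted p = 0.0792). TMM scaling called 3 genes, LAMP3, BEX2 and DQ582201, and quantile normalization 4, these and GDF15. BEX2 was the 1 gene called with a pseudocount of 5. After the GC correction 1551 of 13757 genes had an unadjusted p under 0.05 (limma) and 0 were called. The same 4 genes were called without either low pH library. Fits without a starvation library rest on 1 line for that condition, so their calls are not given. The unadjusted count was 163 without the AsPC-1 control, 1486 without the PANC-1 hypoxia library and 1500 without the AsPC-1 hypoxia library. Counted without a test, 101 genes moved at least 2-fold the same way in both lines, 65 higher and 36 lower, where independent lists would share 18.4 and 24.2. In PANC-1 alone 331 genes were higher and 326 lower, and in AsPC-1 817 and 1090. The polyamine acetyltransferase gene SAT1 was at 1.85 ± 0.33, KLHL24 at 1.96 ± 0.40, ABTB1 at 1.47 ± 0.41 and DKFZp586A1021 at 1.46 ± 0.37. FAM111B was at -1.65 ± 0.38, POP1 at -1.50 ± 0.34, the CTP synthase CTPS (now CTPS1) at -1.47 ± 0.37, hNp95 (the UHRF1 locus) at -1.43 ± 0.33 and PMEPA1 at -1.42 ± 0.35. VEGFA was at 1.23 ± 0.40 and NDRG1 at 1.30 ± 0.48. TXNIP was at 0.78 ± 0.42, ACSS2 at 0.52 ± 0.34, HMGCS1 at 0.25 ± 0.36 and MKI67 at -0.22 ± 0.41, and CA9 went from 8.46 to 2.07 FPKM in AsPC-1 and was listed at 0 in PANC-1.

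**Figure D2:**
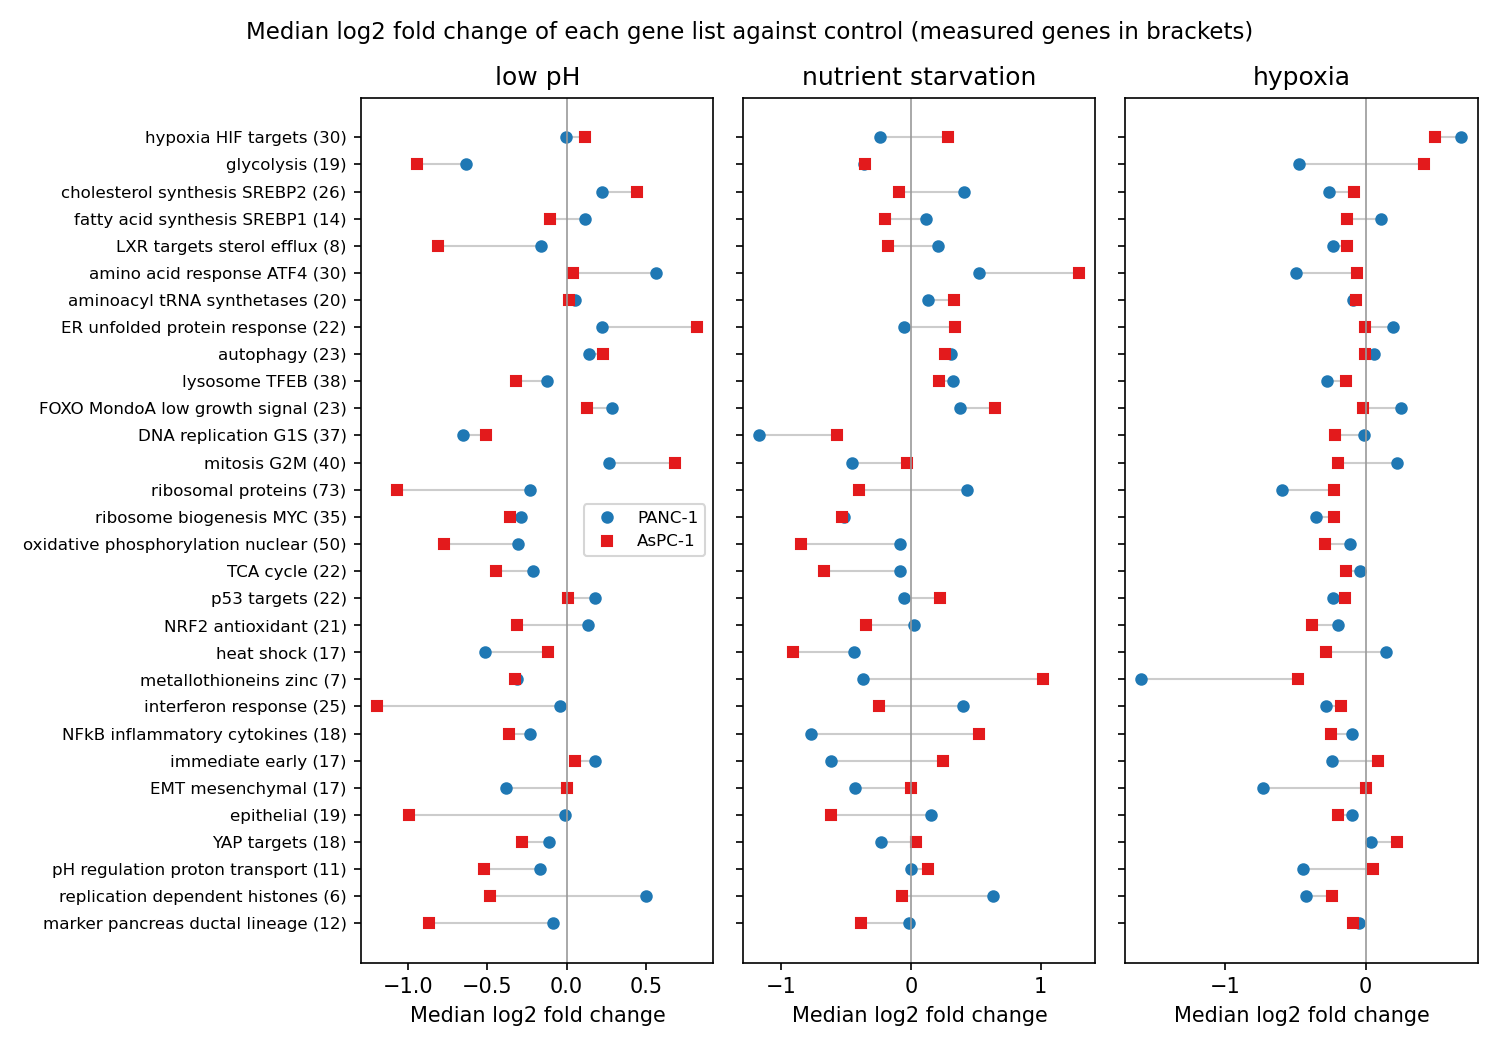
Median log2 fold change against control (x axis) of each gene list of at least 5 measured genes, for PANC-1 (circles) and AsPC-1 (squares) in the 3 conditions. HIF targets under hypoxia stand at 0.68 and 0.49, the amino acid response under starvation at 0.53 and 1.30, and NF-kB genes under starvation on opposite sides of 0.

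Hypoxia was set against control to ask how low oxygen alters expression. Of 30 measured targets of HIF, the transcription factor of low oxygen, 18 were above control in both lines and 2 below it in both. EGLN3, a prolyl hydroxylase of HIF (chromosome 14, 34393423 to 34420032), went from 0.472 to 2.51 FPKM in PANC-1 and from 3.51 to 14.2 FPKM in AsPC-1, a log2 fold change of 1.50 ± 0.39 (SE, n = 2 lines). Of these targets 6 rose when adjusted over the list alone and 0 over all genes (limma, Benjamini-Hochberg). Besides EGLN3 these were the pyruvate dehydrogenase kinase PDK1 at 1.50 ± 0.39, the collagen prolyl hydroxylase P4HA1 at 1.40 ± 0.33, ERO1L (now ERO1A) at 1.25 ± 0.40, the mitophagy receptor BNIP3L at 1.23 ± 0.34 and ANKRD37 at 1.16 ± 0.34. The list median was 0.67 (camera adjusted p = 2.03e-11, adjusted p = 0.58 with an estimated correlation), 0.68 in PANC-1 and 0.49 in AsPC-1, and 0.69 after the GC correction. Over the list alone, 0 rose without either control, 2 without the PANC-1 hypoxia library, 4 without either low pH library and 10 without the AsPC-1 hypoxia library. With no filter on low values or no cell line term 0 rose over the list alone, while 3 did at a mean of at least 5 FPKM and 9 after the GC correction. CA9 was listed at 0 in both PANC-1 libraries and went from 8.46 to 25.6 FPKM in AsPC-1, and VEGFA was at 0.01 ± 0.40. LDHA was at 1.10 ± 0.34 and PGK1 at 1.02 ± 0.34. The glycolysis list was not called (camera adjusted p = 0.183), with medians of -0.47 in PANC-1 and 0.42 in AsPC-1, while its median over both lines was -0.09 and its camera direction up. After the GC correction the glycolysis medians were 0.20 in PANC-1 and 0.32 over both lines, and the list was called (camera adjusted p = 5.06e-07, adjusted p = 0.29 with an estimated correlation), while 0 members passed over the list alone.

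Lists of metal-binding, ribosomal and respiratory genes had medians below control under hypoxia. The 7 metallothionein and zinc genes had a median of -0.92 (camera adjusted p = 0.0085, adjusted p = 0.962 with an estimated correlation), and MT1X and MT1E fell by 1.41 ± 0.46 and 1.12 ± 0.34 when adjusted over the list alone. Over the metallothionein list alone 0 passed without either control, without the PANC-1 hypoxia library, after the GC correction, with a pseudocount of 5, with no filter on low values or with no cell line term, 3 fell without either low pH or either starvation library, and 1 rose and 5 fell without the AsPC-1 hypoxia library. The median of 6 of these genes was -0.61 after the GC correction (camera adjusted p = 5.74e-06, adjusted p = 0.368 with an estimated correlation). The camera call of that list ended without the PANC-1 control, at -0.70 (adjusted p = 0.254), without the AsPC-1 hypoxia library, at -1.43 (adjusted p = 0.173), and with no cell line term (adjusted p = 0.675). The 73 ribosomal protein genes had a median of -0.42 (camera adjusted p = 6.34e-05), the 35 genes of ribosome biogenesis -0.21 (camera adjusted p = 0.0249) and the 50 oxidative phosphorylation genes -0.23 (camera adjusted p = 0.0312), with 56, 16 and 28 of them lower in both lines. The 23 targets of FOXO and MondoA had a median of 0.16 (camera adjusted p = 0.0249), 0.25 in PANC-1 and -0.02 in AsPC-1, with 9 higher in both lines and TXNIP at 0.89 ± 0.42. For these 4 lists the adjusted p = 0.962 with an estimated correlation, and 0 members passed over all genes or when adjusted over the list alone. The ribosomal protein median was -0.28 after the GC correction (camera adjusted p = 9.1e-12, adjusted p = 0.738 with an estimated correlation), and in PANC-1 it went from -0.59 to -0.33. Without the PANC-1 hypoxia library the ribosomal protein median was 0.01, the oxidative phosphorylation median -0.05 and the FOXO and MondoA median 0.02, and these calls ended. That fit sets the AsPC-1 hypoxia library against a control level fitted over both lines. Against the AsPC-1 control library itself, the AsPC-1 medians of these lists were -0.22, -0.29 and -0.02. In the fit without the AsPC-1 control the medians of these lists were -0.16, 0.05 and 0.13, and the calls ended too. Without the AsPC-1 hypoxia library the oxidative phosphorylation call ended at -0.41 (adjusted p = 0.0562) and the FOXO and MondoA call at 0.35 (adjusted p = 0.0635). The ribosome biogenesis call ended without the PANC-1 control, at -0.26 (adjusted p = 0.077), without the AsPC-1 control, at -0.25 (adjusted p = 0.0583), without the AsPC-1 hypoxia library, at -0.37 (adjusted p = 0.131), with a pseudocount of 0.1 (adjusted p = 0.0772) and with no cell line term (adjusted p = 0.135). The oxidative phosphorylation call also ended with a pseudocount of 0.1 (adjusted p = 0.0915) and with the sum of the entries of a symbol (adjusted p = 0.0918), and the FOXO and MondoA call with no cell line term (adjusted p = 0.0922).

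The PANC-1 hypoxia library stood apart from the other 7. In it 2652 genes were at least 2-fold lower than control and 229 higher, while AsPC-1 had 31 lower and 79 higher. The fold change in PANC-1 declined with transcript GC content, with a Spearman rho across 13757 genes of -0.879, while AsPC-1 gave -0.0760. The median log2 fold change in PANC-1 was 0.66 in the class of genes with the lowest GC content and -1.41 in the class with the highest. Ribosomal protein gene RPS28 was at -4.03 in PANC-1 and -0.22 in AsPC-1, and the macrophage inhibitory factor MIF at -3.37 and 0.68. After the GC correction these PANC-1 values were -3.27 and -1.66.

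**Figure D3:**
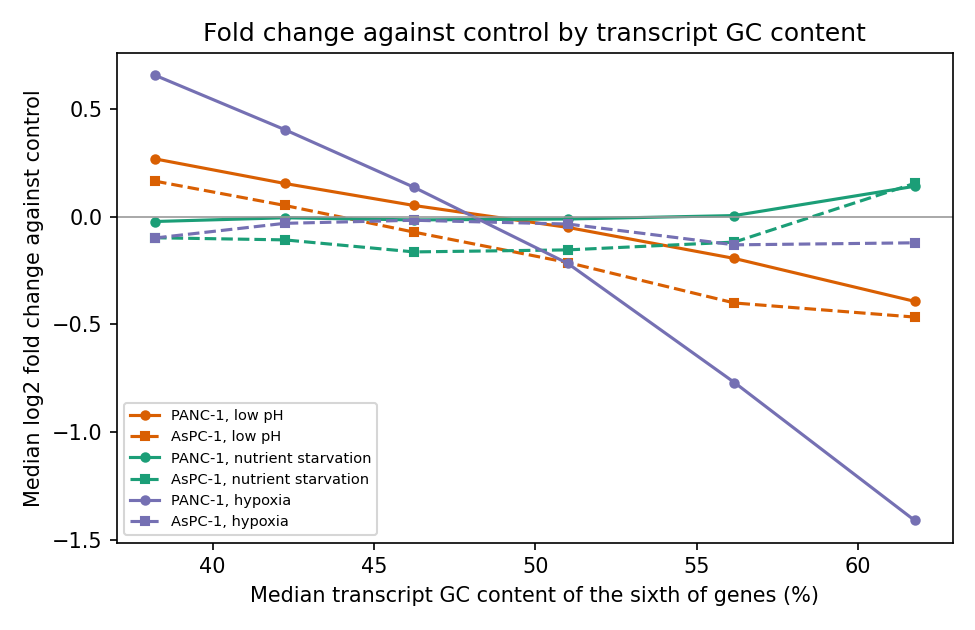
Median log2 fold change against control (y axis) of 6 equal classes of genes ordered by transcript GC content (x axis, percent), for each line and condition. PANC-1 under hypoxia runs from 0.66 to -1.41 and AsPC-1 under hypoxia from -0.098 to -0.12.

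For hypoxia, limma called 0 of 14678 genes at an adjusted p under 0.05, with a smallest adjusted p of 0.750, and 866 at an unadjusted p under 0.05. A fit to only the 4 libraries of this comparison called 11 genes, all lower. It used no GC correction, while fold changes in PANC-1 declined with GC content. A fit without the AsPC-1 hypoxia library rests on PANC-1 alone, where fold changes declined with GC content, so its calls are not given. The unadjusted count was 214 after the GC correction. Counted without a test, 11 genes moved at least 2-fold the same way in both lines, 7 higher and 4 lower, where independent lists would share 1.23 and 5.60. Quantile normalization gave 17 higher and 2 lower, and moved the median of all genes in PANC-1 from -0.0056 to 0.16. The GC correction gave 10 higher and 1 lower among the 13757 genes with a GC value. Among genes above control in both lines were NDRG1, a stress gene also entered as Cap43, at 1.23 ± 0.48 and 1.36 ± 0.49, and LPP, a gene of focal adhesions, at 1.38 ± 0.44. The values of the lower genes that follow are without the GC correction. Among those below control in both lines, besides MT1X, were ATHL1 at -1.59 ± 0.53 with the overlapping FLJ00345 at -1.58 ± 0.53, and PABPC1L at -1.29 ± 0.43 with the overlapping C20orf119 at -1.16 ± 0.42. So were the retinal reductase gene DHRS3 at -1.15 ± 0.52, PILRB at -1.12 ± 0.40 and clusterin, CLU, at -1.07 ± 0.44. ASNS was at 0.34 ± 0.42, DDIT3 at -0.46 ± 0.41, HMGCS1 at 0.24 ± 0.36, ACSS2 at -0.28 ± 0.34 and MKI67 at 0.13 ± 0.41.

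The responses of PANC-1 and AsPC-1 were set side by side to ask whether both lines answer a condition alike, and no difference between them was tested. Under starvation the growth factor gene HBEGF had a log2 fold change of -2.81 in PANC-1 and 2.71 in AsPC-1, and the cell cycle inhibitor CDKN1A -1.99 and 1.97. The transcription factor ETS1 stood at -1.53 and 2.24, CDCP1 at -2.12 and 1.59 and the thrombomodulin gene THBD at -1.28 and 2.54. PPL, a gene of cornified envelopes, stood at 4.32 and 0.52, while FABP4, TSPAN8, PPP1R1B and CYP1A1 stood at -4.35, -2.96, -3.34 and -3.73 in AsPC-1. In PANC-1 these stood at -0.053, 0.72, 1.13 and -0.066. At low pH the interferon-induced OASL stood at 0.30 in PANC-1 and -3.19 in AsPC-1, and TRIM31 at 0 and -3.24. FABP4 was at -4.02 and PPP1R1B at -3.26 in AsPC-1 at low pH. In PANC-1 FABP4 was at the same -0.053 at low pH and under starvation. A gene hardly expressed in PANC-1 could not show a fall there, so such pairs do not show that the lines answer differently. That limit does not cover PPP1R1B and TSPAN8 under starvation, which were above control in PANC-1. EIF2C2 (now AGO2), an Argonaute gene, was at -0.02 in PANC-1 and 2.46 in AsPC-1, and the cyclin gene CCNT1 at 0.21 and 2.42. XTP2, SEC34 (now COG3) and TAOK1 were at 2.35, 2.72 and 2.26 in AsPC-1. Under hypoxia the glycogen phosphorylase PYGL stood at 1.67 in PANC-1 and -0.57 in AsPC-1, and the proteoglycan gene SRGN at 0.50 and -2.08, which were -0.13 and -1.98 after the GC correction. PLEC1 (now PLEC) was at -3.30 and 0.44, and -1.52 and 0.56 after the GC correction.

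Across 14678 genes the log2 fold changes of both lines correlated with a Pearson r of 0.455 at low pH, 0.166 under starvation and 0.128 under hypoxia. After the GC correction these were 0.363, 0.141 and 0.119. PANC-1 under hypoxia correlated with AsPC-1 at low pH with an r of 0.323, which was 0.0953 after the GC correction. PANC-1 at low pH correlated with AsPC-1 under starvation with an r of 0.162, which was 0.255 after the GC correction, while PANC-1 under starvation and AsPC-1 at low pH gave -0.023, and 0.01 after it. Genes are not independent replicates, so no p was attached to these values. Within a line the conditions share 1 control library. Within AsPC-1 the r was 0.537 for low pH with starvation, 0.505 for low pH with hypoxia and 0.460 for starvation with hypoxia. In PANC-1 these were 0.230, 0.536 and -0.080. Simulated noise of equal spread with a shared control gives about 0.50 by construction, so these r decide nothing. In AsPC-1 the covariance was 0.263 for low pH with starvation, against a simulated 0.148. It was 0.111 for low pH with hypoxia and 0.0948 for starvation with hypoxia, against 0.148 and 0.149. In PANC-1 the covariances were 0.0517, 0.209 and -0.0312 in that order, against 0.148 each. The noise took its spread from the fit over both lines, so a shared control was neither shown nor excluded as the whole source.

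AsPC-1 was set against PANC-1 to ask how the lines differ whatever the medium. The intestinal cadherin CDH17 averaged 797 FPKM over the 4 AsPC-1 libraries (557 to 1029) and 0.153 FPKM in PANC-1. AsPC-1 also held the protease inhibitor SERPINE2 at 765 FPKM against 0.985, the hemidesmosomal collagen COL17A1 at 365 against 0.167 and the peptidase DPP4 at 110.04 against 0.00342. SULF2, GCNT3, AKR1C2 and AKR1C3 averaged 222, 124, 207 and 267 FPKM in AsPC-1. PANC-1 held lactate dehydrogenase B, LDHB, at 383 FPKM against 0.0222 in AsPC-1, the mitophagy gene BNIP3 at 95.5 against 0.00702, and the matrix protein SPARC at 79.3 against 0.0738. The serine synthesis enzyme PHGDH averaged 94.5 FPKM in PANC-1 and 0.136 in AsPC-1, and BASP1 43.7 and 0. FBXO27, FBXO17 and MTF (now MT1L) averaged 108, 77.2 and 174 FPKM in PANC-1. Counts of genes apart used FPKM + 1. By this rule 10 of 19 epithelial genes were at least 2-fold higher in every AsPC-1 library than in any PANC-1 library and 0 the other way. EPCAM was at 314 FPKM in AsPC-1 and 9.96 in PANC-1, and CDH1 at 12.4 and 0.921. ESRP2 went the other way, at 3.86 FPKM or more in PANC-1 and 1.57 or less in AsPC-1, and missed the rule only through the added 1 FPKM. Of 17 mesenchymal genes, 8 were higher in PANC-1 by this rule, such as CDH2 at 4.42 against 0.000663 and MMP2 at 37.8 against 0. SNAI2 was higher in AsPC-1, at 36.7 against 0.284. In FPKM itself SNAI1 (lowest 1.57 in PANC-1, highest 0.469 in AsPC-1) and COL6A2 (0.963 and 0.0108) were also higher in PANC-1. The ranges of VIM overlapped, at means of 2444 in PANC-1 and 1925 in AsPC-1. Of 12 ductal genes, 7 were higher in AsPC-1, such as CEACAM5 at 9.47 FPKM against 0, and FOXA2 was higher in PANC-1, at 7.58 against 0. Over all 14678 genes, 726 were higher in AsPC-1 by this rule and 915 in PANC-1, 1641 in all. With 0.1 FPKM added in place of 1 the numbers were 898 and 1177. The larger number changed sides with TMM scaling, at 905 in AsPC-1 and 758 in PANC-1, and at a mean of at least 5 FPKM the numbers were 453 and 447. Of the splits of 8 values into 4 and 4, 2.86% have no overlap by chance. The libraries of a line are not independent cultures and the rule also asks for a 2-fold gap, so this share is no chance level for the counts.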

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

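The tests on transcript length and on the GC trend in AsPC-1 were chosen after the GC-corrected results had been seen, and the other tests of this part before their results were seen.

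Under starvation several responses went opposite ways in the lines, none of them tested as a difference. HIF target genes had a median log2 fold change of -0.24 in PANC-1 and 0.28 in AsPC-1, -0.52 apart, and NF-kB and cytokine genes -0.77 and 0.53, -1.30 apart. These lists were chosen because their medians lay beyond nearly all random lists of like expression, on opposite sides in PANC-1 and AsPC-1. That position is the rule of choice, so it adds no evidence of a difference. Random lists also lack the correlation between genes of a list, estimated at 0.466 for NF-kB and cytokine genes and 0.0744 for HIF targets. Genes at least 2-fold from control in opposite directions numbered 53 under starvation, 28 of them lower in PANC-1, where 18.2 would be shared by independent lists, and 25 higher in PANC-1, where 24.6 would be. They included HBEGF and CDKN1A and, chosen after its values were seen, EREG (-1.20 in PANC-1 and 2.11 in AsPC-1). Low pH gave 4 such genes, each higher in PANC-1 and lower in AsPC-1, IFIT2 (1.02 and -2.04), IFITM1 (1.31 and -1.53), RGS2 (1.26 and -1.50) and SRGN (1.15 and -2.10), chosen after their values were seen, where 29.6 would be shared. Their PANC-1 values were 0.86, 1.50, 1.09 and 0.88 in that order after the GC correction. Hypoxia gave 5, each lower in PANC-1, ANGPTL4 (-1.10 and 1.05), HSPG2 (-2.44 and 1.36), U48725 (-2.54 and 1.03), U48729 (-1.92 and 1.24) and VISA (-1.42 and 1.18), also chosen after their values were seen, where 14.3 would be shared. In PANC-1 after the GC correction ANGPTL4 was at 0.42, so no longer lower, HSPG2 at -1.08 and VISA at -1.09, while U48725 and U48729 have no GC value. Antisense entries, which no comparison used, held 1.80% of aligned bases in PANC-1 and 1.81% in AsPC-1 under starvation, above the 1.58% and 1.65% of the controls, while the AsPC-1 low pH library held 1.08%, the least of the 8. That library also had the fewest genes at 1 FPKM (12619), and a cause was not tested.

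In PANC-1 under hypoxia 2527 genes with a GC value were at least 2-fold lower, and 7.24% of them were so after the GC correction, which removes a trend on GC content whatever its cause and so decides nothing here. Between transcripts of the same gene, the fold change in that library also fell with GC content, with a rho of -0.469 over 4375 genes against 0.205 in AsPC-1. Regulation of whole genes would not give this trend within genes, but the values within genes cannot exclude it as a source of the trend between genes. In PANC-1 the slope was -0.0376 log2 per GC percentage point within genes and -0.0838 between genes. The bootstrap interval of the PANC-1 rho within genes, from 1000 resamples of genes, was -0.490 to -0.450. It covers spread between genes, not between cultures. The AsPC-1 hypoxia library had a rho across genes of -0.0760, which argues against low oxygen by itself giving the trend between genes in any line. A GC bias of the PANC-1 hypoxia library is a candidate explanation for part of these lower values. A response of PANC-1 alone that favours transcripts of low GC content stays open, since there is 1 library.

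At low pH the fold changes of both lines correlated with an r of 0.455. The correlation was 0.363 after the GC correction and 0.369 after a correction for GC content and length, so a shared bias on these features is unlikely to be its whole cause. Between unlike conditions the r after the GC correction was 0.255 for PANC-1 at low pH with AsPC-1 under starvation, 0.01 for the reverse pair, 0.0953 for PANC-1 under hypoxia with AsPC-1 at low pH and 0.0489 for the reverse. A response to acid medium, in part shared with other stresses or not, stays open as a hypothesis. Other effects common to both low pH libraries, such as a batch or the handling of both cultures, were not tested and stay open.

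The median of the HIF target genes was above 0 in both lines under hypoxia, and 18 of 30 were higher in both. In PANC-1 their median was 0.80 after the GC correction, with a bootstrap interval of 0.57 to 1.12 from 1000 resamples of the genes of the list. That interval covers spread between genes in a single pair of libraries, not between cultures. After a correction for GC content and length the lower of the medians of both lines was 0.58, that of AsPC-1. These medians argue against such bias as the whole cause. A response to low oxygen may account for them, as a hypothesis, while effects of single cultures stay open.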

How the results depend on the processing

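The GC corrections, the transcript chosen by the authors and the genes by RefSeq accession were chosen after the data were seen, and the other alternatives before the data were examined. A count-based test was not run because the files hold aligned bases, not read counts. Over the alternatives of 33 list medians, 694 values kept their direction and their side of the threshold, 59 kept the direction and lost the call, and 6 changed direction. Over those of 75 values of named genes, 1624 kept the direction and again did not pass, 51 kept the direction and passed the threshold, and 18 changed direction. None of these genes passed in the main fit, so no call could be lost, and sizes were not compared. Where a result moved, the cause was not tested.

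No list was called in any condition with an estimated correlation (0 at low pH, 0 under starvation, 0 under hypoxia) or with fry (0, 0 and 0), against 15, 12 and 6 with the preset one. Under hypoxia 3 lists were called with no cell line term and 12 after the GC correction. Genes past the threshold numbered 351 at low pH and 11 under hypoxia with only the 4 libraries of the comparison. Under starvation they numbered 1 with a pseudocount of 5, 3 with TMM scaling and 4 with quantile normalization. Genes 2-fold from control in both lines numbered 459, 218 and 32 at low pH, under starvation and under hypoxia with a pseudocount of 0.1, and 49, 24 and 2 with one of 5. At low pH they were 103 after the GC correction, with or without the PANC-1 hypoxia library, and under hypoxia 19 with quantile normalization and 7 with the transcript chosen by the authors. Genes apart between the lines numbered 900 at a mean FPKM of at least 5, which leaves fewer genes.

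Only lists called by camera with the preset correlation entered the comparison of list medians, so the 6 that changed direction belong to such lists by construction. With the GC correction and without the PANC-1 hypoxia library, the hypoxia values were 0.028 for the ribosomal proteins, -0.10 for VEGFA, -0.28 for ASNS and -0.16 for MKI67, and VEGFA was at -0.0096 with the correction alone.

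Leaving out each library in turn, where a lone library of a condition is assumed to vary like the others, gave 0 to 1 genes past the threshold at low pH, 0 to 60 under starvation and 0 to 1477 under hypoxia, and 3 to 10 lists under hypoxia. List medians ranged from -0.083 to 0.77 for the amino acid response and -1.02 to 0.0062 for interferon genes at low pH, -0.45 to 0.037 for mitosis under starvation, and -0.88 to 0.011 for ribosomal proteins and -0.50 to 0.052 for oxidative phosphorylation under hypoxia. At low pH NDRG1 ranged from -0.026 to 1.34 and MKI67 from -0.033 to 1.22. Under starvation CA9 ranged from -1.71 to 0.091, HMGCS1 from -0.086 to 0.58 and MKI67 from -0.84 to 0.41. Under hypoxia CA9 ranged from -0.43 to 1.92, VEGFA from -0.23 to 0.26, ASNS from -0.25 to 0.93, HMGCS1 from -0.012 to 0.50 and MKI67 from -0.50 to 0.75. Depth limits values under 1 FPKM most in the PANC-1 starvation library, where 1 FPKM on 1 kb rests on 27.1 fragments.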

Other observations

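Under starvation IRF7, a regulator of interferon genes, was at 1.68 ± 0.43 and ISG15 at 1.22 ± 0.59, while 0 of 25 interferon response genes passed and the list was not called (camera adjusted p = 0.551, adjusted p = 0.903 with an estimated correlation). At low pH STAT2 was at 1.16 ± 0.34, while IFITM3 and OAS1 were at -2.26 and -2.32 in AsPC-1. Among aminoacyl-tRNA synthetases, which charge tRNAs for translation, SARS was at 1.30 ± 0.38 and AARS at 0.99 ± 0.33 under starvation, and that list was not called either (camera adjusted p = 0.0984, 0 of 20 passed). The desaturase gene SCD was at 0.90 ± 0.34 at low pH and 0.86 ± 0.34 under starvation, and SREBF1 at 1.23 ± 0.47 under starvation, while the list of fatty acid synthesis had a median of -0.05 in both conditions and was not called (camera adjusted p = 0.34 and 0.705). The metallothionein gene MT2A was at -0.88 in PANC-1 and 2.12 in AsPC-1 under starvation. The p53 targets TP53INP1 and BBC3 were at 1.12 ± 0.31 and 1.00 ± 0.34 under starvation, while CDKN1A was at -1.99 in PANC-1 and 1.97 in AsPC-1. The p53 list had a median of -0.0076 and was not called (camera adjusted p = 0.303), with 5 of 22 genes higher in both lines and 4 lower in both.

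Markers of other cell types were mostly low. CD68, a lysosomal protein also used as a leukocyte marker, measured 126 FPKM in the PANC-1 control and 81.9 in the AsPC-1 control. LUM, a proteoglycan used as a fibroblast marker, measured 199 FPKM in the AsPC-1 control, 20.2 under starvation, and was listed at 0 in the 4 PANC-1 libraries.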
